A study of Mus musculus with 8 samples.

How the data were processed

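Gene expression was measured in the cortex of 8 newborn mice, 4 labelled control and 4 labelled ischemia, with 1 one-colour Agilent 8x60K mouse array per sample. Per the labels, all 8 were males of the inbred strain C57BL/6NCr taken at postnatal day 1.5. For the ischemia group the uterine arteries of the pregnant mother were closed with clips for 14 min under anesthesia at embryonic day 16.5. The labels do not say whether control mothers were operated on without occlusion, nor which pups shared a mother. P-values therefore measure the spread between the sampled pups, and any litter effect is part of that spread or of the group difference. Per the labels' protocols, 50 ng of total RNA was amplified and labelled with the dye Cy3 with a low-input kit.

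Per the file headers and the submitters' processing notes, the scans were read with Agilent Feature Extraction 10.7.3.1. The values used are the intensities that the authors deposited, on a linear scale: the processed signal of each spot, which the software has corrected for background, and for an alternative the mean signal and the median local background signal. The deposited files also flag each spot as well above background, saturated, non-uniform or a population outlier. The authors' value table is a ratio: tested on the files, each of its columns equals the processed signal divided by 1 constant per array, to within 0.362%. Its medians per array lie between 0.0836 and 0.1003. What that constant stands for is not given in the sources used here. The direction is that of the signal, and the table was used only as an alternative.

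Each array held 59305 non-control spots of 55681 probes. Control spots were left out, and 26 probes with a flagged outlier spot on every replicate spot of any array were dropped. Spots of the same probe were averaged. Values were taken as log2 of the processed signal minus the log2 of the array's 75th percentile, which ranged from 305.6 to 393.3. Between 47.6% and 51.7% of the non-control spots per array were well above background, and 0 were saturated. The software marked 134 to 144 spots per control array and 165 to 189 per ischemia array as non-uniform or population outliers, a difference that slide row and group share. Negative control spots averaged between 41.8 and 45.7. The median coefficient of variation of probes with 10 spots lay between 4.91% and 5.60%. The number of arrays limits the precision. A probe was kept when it was well above background on at least 4 of the 8 arrays, which left 27131 probes. Of a gene's kept probes the one with the highest mean was used, which gave 19751 genes.

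Probe names were updated with a table of RefSeq genes of assembly GRCm38.p6, used for names only. Of the probes, 27235 were named through their accession, 3581 through a current symbol and 565 through a single older symbol, and 24300 kept the name in the files. Coordinates are those of the probes in the files, which use mm9, and are counted from 1. Whether a probe lies in an exon or a UTR was not analysed here, since no mm9 annotation was used.

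The groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Before the data were examined, 41 gene lists were written, of responses, cell types, neighbouring tissues and technical gene classes. Of these, 40 were tested and the list of Y-linked genes with Xist served as a check of the labelled sex. Lists were compared with limma's camera, two-sided, with its preset correlation of 0.01 and adjustment over the lists with at least 5 measured members. The mean of each list per array was compared with an exact two-sided permutation test over the 70 assignments of the labels, whose smallest p is 0.0286. A test for enrichment among called genes was planned for 20 or more genes passing in 1 direction and was not run, since fewer passed. Fisher's exact test therefore gave no value.

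The genes named were chosen by a rule fixed before the data were examined. With fewer than 20 genes passing, these are each gene that passed, the 10 rising and 10 falling genes with a symbol and the smallest unadjusted p, in each list described the members that passed or else the 2 with the smallest p, 16 genes fixed in advance, of which 1 is not reported here, and 4 genes for the sex check. Other genes are named as chosen after their values were seen. A fold against a group in which a probe was well above background on 0 arrays is a floor estimate. It holds for the main background correction only and is no strict bound, since normexp gave smaller differences. It sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value of any probe well above background.

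The alternatives were other background corrections, scalings, filters, probe rules, variance models, thresholds and set tests, the replicate number as a block, array weights, the authors' value table and each array left out in turn. For arrays left out, a probe had to be well above background on at least 4 of the remaining arrays. The normexp correction added an offset of 50 to every signal, which shrinks log differences of dim probes by construction. Smaller values and lost calls with normexp can stem from this offset. All 8 arrays lay on 1 slide and came from 1 scan. Controls filled slide row 1 and ischemia arrays slide row 2, so row and group cannot be told apart. The functions were tested on simulated data drawn from the means and spreads of the 19751 genes, in 10 simulations with 200 changed genes each. Of the changed genes, 61.2% were recovered at 1.5-fold, 83.8% at 2-fold, 94.6% at 3-fold and 95.4% at 4-fold, with 9 false calls per simulation on average. The simulated noise was independent between genes, which that of real arrays is not. With 200 changed genes the adjusted threshold is also easier to reach than where few genes change. Recovery in the real data can therefore be lower, and these shares do not show which folds would be missed there. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.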

Results

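The comparison asks how a short interruption of the uterine blood supply at E16.5 left gene expression in the cortex of mouse pups at postnatal day 1.5. Each group held 4 arrays, 1 per pup. Transcripts of the male-specific genes Ddx3y and Eif2s3y were well above background on 8 of 8 arrays and those of Xist on 0 of 8, as the labelled sex requires. The Kdm5d probe was well above background on 0 of 8 arrays.

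Few differences between the groups passed the adjusted threshold. Of 19751 genes, 1 passed the test, a non-coding RNA feature of the array known only by its position, with a probe on chromosome 18 from 63526037 to 63526096 in mm9. It fell by 0.73 on the log2 scale in the ischemia group (SE 0.06, limma adjusted p = 0.0337, 4 arrays per group) and lay lower in 4 of 4 ischemia arrays than in any control. With limma, 0 genes were called higher. At an unadjusted p under 0.05 there were 2151 genes, 641 higher and 1510 lower, where 988 are expected by chance. The groups did not overlap in 1294 genes, or 6.55%, where chance gives 2.86%. The median log2 difference over all genes was -0.02. With normexp background correction the chromosome 18 feature differed by -0.35 (limma adjusted p = 0.112), where the offset of 50 shrinks so dim a probe. The single call was lost when any 1 of the 8 arrays was left out, when 0 genes passed. Of the 35 ways to split the 8 arrays into groups of 4, the real one included, 2 gave as many genes past the threshold and 2 as many at an unadjusted p under 0.05.

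The 10 genes higher in ischemia with the smallest p did not pass the test, and lie above the controls in all ischemia arrays in part because they were chosen by p. Under other settings Pla1a and Chil3 passed with median scaling, and Pla1a and Slco2a1 with a trended and robust variance. With normexp the differences were 0.67 for Pla1a, 0.33 for Chil3, 1.10 for Sult1a1, 0.31 for Slco1a4 and 0.29 for Col7a1. Its offset of 50 shrinks dim probes by construction. For Chil3 and Slco1a4, not measured above background in the controls, these values are not exact. Chil3, a chitinase-like protein of myeloid cells, was well above background on 0 of 4 control arrays and on 4 of 4 ischemia arrays (limma adjusted p = 0.0994). By the floor estimate it was about 1.5-fold higher in ischemia. Pla1a, a phosphatidylserine-specific phospholipase, differed by 1.43 (SE 0.16, adjusted p = 0.0994). The sulfotransferase Sult1a1 differed by 1.74 (SE 0.33, adjusted p = 0.221). The prostaglandin transporter Slco2a1 differed by 0.72 (SE 0.11). By the floor estimate the barrier organic anion transporter Slco1a4 was 1.87-fold higher, with 0 of 4 control arrays well above background. The collagen gene Col7a1 differed by 0.52 and Sgms1, a sphingomyelin synthase, by 0.53, although a second probe of Sgms1 gave -0.27. Inpp1 differed by 0.42, Prepl by 0.32 and Slc25a27, a mitochondrial carrier, by 0.31.

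The 10 lower genes with the smallest p did not pass either, although Tubb6, Fam13c, Tk1 and Col22a1 passed with a trended and robust variance (adjusted p from 0.0165 to 0.0356). With normexp the differences were -0.57 for Ctsw, -0.43 for Chil1, -0.42 for Pfn3, -0.30 for Timp1 and -0.29 for Kcnq1, dim probes that its offset shrinks. Ctsw, a cathepsin of cytotoxic lymphocytes, differed by -0.93 (SE 0.13, adjusted p = 0.151). The tubulin gene Tubb6 differed by -0.86 (SE 0.11, adjusted p = 0.134) and Chil1 by -0.84 (SE 0.13, adjusted p = 0.151). Pfn3, a profilin, differed by -0.69, the metalloproteinase inhibitor Timp1 by -0.63 and the collagen gene Col22a1 by -0.63. Tk1, the thymidine kinase of dividing cells, differed by -0.62. The potassium channel gene Kcnq1 and Fam13c each differed by -0.54, while a second probe of Fam13c gave 0.15. Evi2a differed by -0.49. Second probes of Col22a1, Tk1 and Kcnq1 gave -0.34, -0.28 and -0.21.

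**Figure D1:**
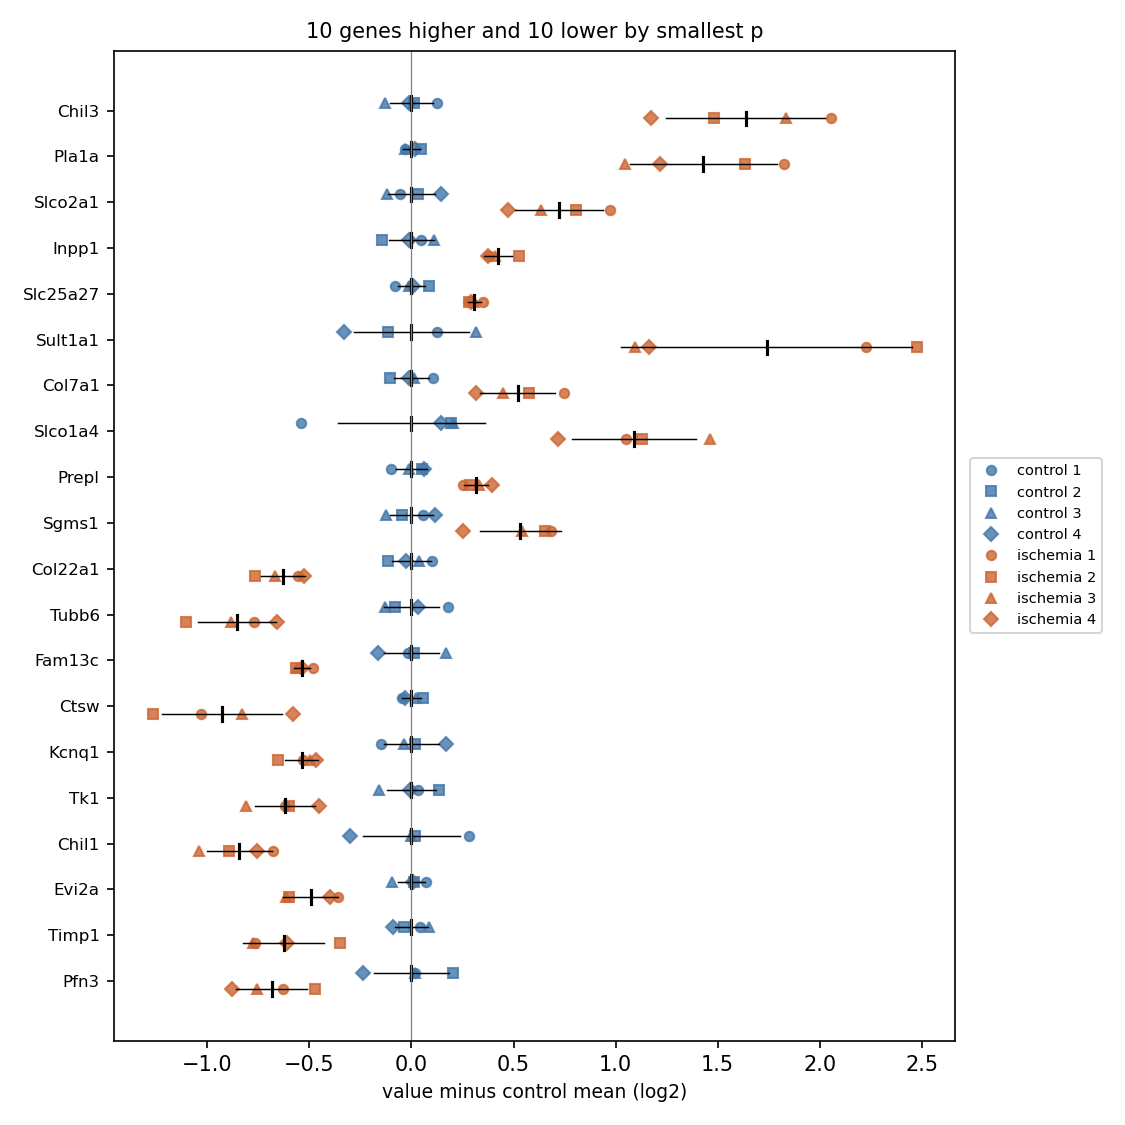
Values of the 10 rising and 10 falling genes on each array, as the log2 value minus the mean of the 4 controls (x axis). Points are arrays, thick bars group means and thin lines 1 SD. Pla1a lay between 1.05 and 1.82 in the ischemia arrays, and the groups do not overlap in any of the 20 genes, which were chosen by their p.

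Camera called 4 of 40 lists between the groups, and as many or more in 34 of the 35 splits of the arrays, the real one included. Camera called the cell cycle list lower, although 0 of its members passed over all genes. Of 33 measured members, 32 were lower in ischemia, 15 of them at an unadjusted p under 0.05, and the list's mean differed by -0.25 (camera adjusted p = 2.31e-09). With an estimated correlation the call was lost (adjusted p = 0.750), and 4 members passed when adjusted over the list alone. Ccnb2, a cyclin of mitosis, differed by -0.50 (SE 0.10) and the spindle checkpoint kinase gene Bub1 by -0.46 (SE 0.10). The list's mean per array was lower in 4 of 4 ischemia arrays than in any control, with an exact permutation p = 0.0286, the smallest the design allows, and an adjusted p of 0.286 over 40 lists.

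Camera called the glucocorticoid response list higher, although 0 of its members passed over all genes. Of 18 measured members, 17 were higher, 7 of them at an unadjusted p under 0.05, and the mean differed by 0.32 (camera adjusted p = 7.54e-07). With an estimated correlation the call was lost (adjusted p = 0.750). Adjusted over the list alone, 6 members passed. Sult1a1 and Nfkbia, the inhibitor of NF-kappaB, are the members with the smallest p, and Nfkbia differed by 0.22 (SE 0.05). The hypoxia-inducible factor gene Hif3a, chosen after its value was seen, differed by 1.51 (SE 0.40). Together with Sult1a1 at 1.74, Hif3a lifted the list's mean above its median of 0.21. Further members chosen after their values were seen differed by 0.00 for Fkbp5, 0.07 for Tsc22d3, 0.08 for Sgk1, 0.05 for Zbtb16 and 0.16 for Klf9, all common targets of the glucocorticoid receptor. Ddit4 and Dusp1, members also singled out after their values were seen, rose more, by 0.27 (SE 0.08) and 0.24 (SE 0.08). Above the control mean, the list's mean lay at 0.38, 0.49, 0.32 and 0.09 in ischemia replicates 1 to 4 (exact permutation p = 0.0286, adjusted p = 0.286).

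Genes of endothelial cells were called higher by camera, with a mean difference of 0.20 (adjusted p = 0.00540). With an estimated correlation the adjusted p was 0.750. Of 26 members, 15 were higher and 11 lower, and adjusted over the list alone 5 passed as higher and 2 as lower. Slco1a4 and Ly6c1, the latter with a difference of 0.84 (SE 0.19), have the smallest p. The receptor gene Kdr and the progenitor antigen gene Cd34, chosen after their values were seen, differed by -0.31 (SE 0.07) and -0.25 (SE 0.07). A second Kdr probe gave -0.12. The call ended without ischemia replicate 1 (difference 0.12, adjusted p = 0.125), without ischemia replicate 2 (0.12, adjusted p = 0.0964) and with probes well above background on all 8 arrays (0.14, adjusted p = 0.0541), and with normexp background correction the difference was 0.12 (adjusted p = 0.00544).

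Genes of the meninges and extracellular matrix were also called higher, with a mean difference of 0.34 (camera adjusted p = 0.00927, adjusted p = 0.750 with an estimated correlation). Of 23 members, 16 were higher, and 0 passed when adjusted over the list alone. Ptgds, a prostaglandin synthase of the meninges, differed by 2.35 (SE 0.87) and the growth factor gene Igf2 by 0.34 (SE 0.13). Ptgds lay 3.83, 0.52, 0.78 and 4.27 above the control mean in ischemia replicates 1 to 4, and 0.78 above it in control replicate 2. The list's mean lay 0.90 above the control mean in ischemia replicate 1 and -0.12 from it in ischemia replicate 2, and the call ended without ischemia replicate 1 (difference 0.13, adjusted p = 0.125), with normexp background correction (0.20, adjusted p = 0.0622), with probes well above background on all 8 arrays (0.26, adjusted p = 0.0541) and, chosen after seeing the data, without ischemia replicates 1 and 4 (0.02, adjusted p = 0.336). Genes of the choroid plexus and ependyma were not called (adjusted p = 0.430), with 7 of 13 higher and a mean of 1.74 above the controls in ischemia replicate 4. Their difference of 0.33 became -0.13 without that array and 0.64 without ischemia replicate 3 (adjusted p = 0.0140). Ttr, the transthyretin gene of the choroid plexus, lay 10.12 above the control mean in that array and Enpp2 0.69.

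**Figure D2:**
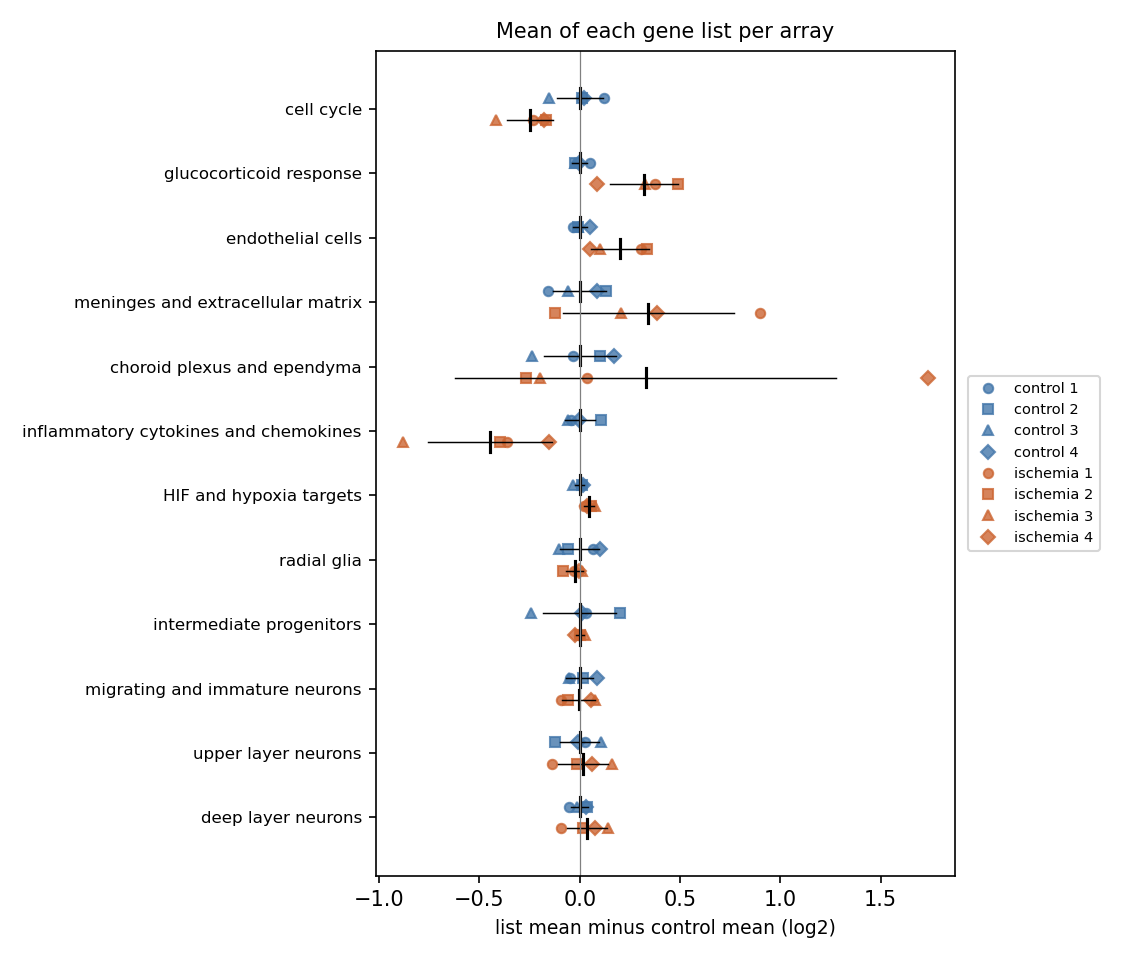
Mean log2 value of 12 gene lists on each array minus the mean of the 4 controls (x axis). Points are arrays, thick bars group means and thin lines 1 SD. The cell cycle list lies between -0.42 and -0.17 in the ischemia arrays, and the choroid plexus list reaches 1.74 in ischemia replicate 4.

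Lists of neurons and progenitors did not pass. Migrating and immature neurons differed by -0.01 on average, with 18 of 31 members higher and the test pointing up (adjusted p = 0.745), and the genes with the smallest p were Gap43 at -0.14 and Draxin at -0.27. Draxin differed by -0.15 without control replicate 2, and its second probe gave -0.09. Upper layer neurons differed by 0.02 (adjusted p = 0.305), with Cited2 at 0.25 and Rasgrf2 at -0.20, where a second Rasgrf2 probe gave 0.02. Deep layer neurons differed by 0.03 (adjusted p = 0.0908), with Grik3 at 0.27 and Fezf2 at 0.23, but by 0.00 without ischemia replicate 3, where the sign turned, and by 0.08 without ischemia replicate 1 (adjusted p = 0.0219). Subplate neurons differed by 0.06 (adjusted p = 0.0796), with Cplx3 at -0.54 and Hpcal1 at 0.23, and by 0.03 without control replicate 2 and 0.10 without control replicate 3. Radial glia differed by -0.03, although the test pointed up (adjusted p = 0.966), with Nes at -0.23 and Fabp7 at -0.22. In intermediate progenitors 9 of 16 members were higher (adjusted p = 0.467), with Dll3 at 0.17 and Mfap4 at -0.32. Mfap4 differed by -0.57 without control replicate 3 and -0.15 without control replicate 2, and a second Dll3 probe gave -0.07.

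None of the following single genes of cortical development, fixed in advance, passed. Reln differed by 0.16 (SE 0.16), Dab1 by 0.12 (SE 0.12), Cux2 by -0.09 (SE 0.12), Bcl11b by 0.02 (SE 0.09), Tbr1 by 0.06 (SE 0.11), Eomes by -0.18 (SE 0.19) and Pax6 by 0.07 (SE 0.22). Over kept probes, Dab1 ranged from -0.10 to 0.14, Cux2 from -0.09 to 0.09, Tbr1 from -0.07 to 0.06 and Eomes from -0.18 to -0.04. Ccn2, a subplate marker formerly named Ctgf, differed by 0.27 (SE 0.12). For Dcx, a microtubule protein of migrating neurons, the value was 0.16 (SE 0.07), and its 3 probes ranged from -0.18 to 0.16. Of the glial genes, Gfap differed by 0.10 (SE 0.18), Olig2 by 0.11 (SE 0.08), Mbp by 0.07 (SE 0.06) and Aif1 by 0.24 (SE 0.11), with the 3 Mbp probes between -0.59 and 0.19. Without ischemia replicate 2 Aif1 differed by 0.13. With 1 array left out in turn, Reln ranged from 0.06 to 0.26, Dab1 from 0.03 to 0.21, Eomes from -0.35 to -0.06 and Olig2 from 0.05 to 0.16, and the sign of Cux2, Bcl11b, Tbr1, Pax6 and Gfap turned in at least 1 case.

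Genes of the hypoxia response did not pass. The HIF targets differed by 0.05 on average, with 16 of 28 members higher (camera adjusted p = 0.104, exact permutation p = 0.0286, adjusted p = 0.286). Ddit4 differed by 0.27 (SE 0.08), Higd1a by -0.20 (SE 0.06), Vegfa by 0.18 (SE 0.08) and Hif1a by 0.00 (SE 0.09). A second Vegfa probe gave 0.02. Of 11 inflammatory cytokines and chemokines 9 were lower, with a mean of -0.45 (camera adjusted p = 0.102, exact permutation p = 0.0286, adjusted p = 0.286). The mean was -0.29 without control replicate 2 and -0.06 with probes well above background on all 8 arrays (adjusted p = 0.764), and camera called the list under 4 of 21 other settings. Adjusted over the list alone, 3 passed as lower and 1 as higher. Ccl4, a chemokine of microglia, was 1.73-fold lower by the floor estimate, with 0 of 4 ischemia arrays well above background. With normexp and its offset it differed by -0.54.

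The interferon response list differed by -0.26 (adjusted p = 0.0953), with Gbp3 at -0.62 and Ifitm3 at -0.46, or -0.26 for Ifitm3 without ischemia replicate 3. The list was called under 6 of 21 other settings and differed by -0.12 without control replicate 2 (adjusted p = 0.328). The unfolded protein response list differed by -0.12 (adjusted p = 0.0577), with Calr at -0.23 and Xbp1 at -0.23, and was called under 10 of 21 other settings, 4 of them with an array left out (lowest adjusted p = 0.00258). Blood cell genes differed by -0.25 (adjusted p = 0.0796), with the globin genes Hba-a2 at -0.54 and Hbb-b2 at -0.57, which have near-identical copies. Over 21 other settings the blood cell list ranged from -0.34 to -0.09 and was called under 4. Astrocyte genes differed by 0.06 (adjusted p = 0.0577), with Sparcl1 at 0.27 and Aldoc at 0.26, and with 1 array left out by 0.01 (without control replicate 3) to 0.11 (without ischemia replicate 3, adjusted p = 0.00117). Microglial genes differed by 0.05 (adjusted p = 0.138), with C1qa at 0.42 and Ctss at 0.34, and by 0.01 without control replicate 1 and 0.08 without control replicate 2 (adjusted p = 0.0347). They went both ways, with 14 higher and 10 lower, of which 4 and 3 had an unadjusted limma p under 0.05.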

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

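The tests of intermediate progenitors, endothelial share, receptor activation, choroid plexus tissue and single spots, and those of other splits for the 2 gene counts, were chosen after the results were seen, as were both settings that address tissue carry-over. Within groups, 248 sets of 4 arrays were checked by Dixon's ratio for 1 array lying apart from the other 3. Such an array was found in 12 sets, where chance would give about 12.4 in independent sets. The sets overlap, and many genes were chosen by p or after their values were seen, so the match does not show that no array stands out. The ratio also passed over Ttr, 10.12 above the control mean in ischemia replicate 4. Ratios for control arrays were 0.923 for Slco1a4 (replicate 1 low), 0.889 for Bub1 (replicate 3 low), 0.933 for Gap43 (replicate 3 high), 0.840 for Draxin (replicate 1 low), 0.877 for Cited2 (replicate 1 low), 0.897 for Reln (replicate 1 low) and 0.954 for Dab1 (replicate 3 high). For ischemia arrays they were 0.886 for Ccnb2 (replicate 3 low), 0.914 for Aif1 (replicate 2 high), 0.836 for Fkbp5 (replicate 3 high), 0.947 for Folr1 (replicate 4 high) and 0.848 for the choroid plexus list (replicate 4 high).

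Choroid plexus transcripts were very high in ischemia replicate 4. Folr1 lay 3.28 above the control mean there and Ttr 10.12. Of the 13 measured members, 4 lay over 2 log2 units above the control mean, each on its own spot, which argues against a defect of single spots. In all, 8 of 13 members were highest in that array, so choroid plexus tissue in that dissection is a candidate explanation. Of these members 11 were also well above background on all 4 control arrays and 1 is in another list. The ependymal members Foxj1 and Rsph1 lay at 0.04 and 0.10 there. No biological explanation was tested.

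The cell cycle list was called lower by camera in the ischemia arrays, a call lost with an estimated correlation (adjusted p = 0.750). Scaling between arrays is argued against as the source of the preset-correlation call by quantile normalization (-0.24, camera adjusted p = 2.22e-09). Normexp (-0.18, camera adjusted p = 5.43e-09) changed the background correction. It scaled each array by 1 constant as before, so it does not test scaling. Median scaling and the authors' table shift each array by 1 constant, so they could hardly change the call and add nothing. Fewer intermediate progenitors stays open: the gap between that list and the cell cycle list differed by 0.25 (SE 0.09, exact permutation p = 0.0857). A later developmental stage stays open too, with a maturation index of 28 genes that rise and 26 that fall with age 0.0302 higher in ischemia (SE 0.0841, exact permutation p = 0.714). The occlusion itself was not separated from slide row, litter or surgery, which go with the groups or are not given.

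The glucocorticoid list was called higher by camera in the ischemia arrays, a call lost with an estimated correlation (adjusted p = 0.750). A larger share of endothelial cells stays open: the endothelial list differed by 0.20 (SE 0.07, exact permutation p = 0.0571), less than the glucocorticoid list's 0.32 but within 2 SE of it, its members went both ways with a median of 0.07 against 0.21, and 10 general endothelial markers, chosen after the results were seen and without the called members, differed by -0.0161 (SE 0.0721). Choroid plexus and meningeal tissue stays open. With both list means as covariates the difference was 0.38 (camera adjusted p = 8.31e-09, preset correlation). That fit cannot decide, since the choroid list mean chiefly marks ischemia replicate 4 (1.74), where the glucocorticoid list rose least (0.09). In ischemia replicate 2, where it rose most (0.49), the choroid and meninges lists lay at -0.27 and -0.12. Receptor activation in all cells stays open, as 5 common targets, too few and chosen after their values were seen, differed by 0.0728 (SE 0.0732), below the list's mean of 0.32 by more than 2 SE and below its median of 0.21 by less than that. A hypothesis left untested is that maternal stress or surgery differed between the groups.

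Other splits of the 8 arrays bear on the counts. The real split is included in each count here. Of the 35 splits, 2 gave at least as many genes at an unadjusted p under 0.05, with 2151 in the real split and 2531 in the highest other. Likewise 2 of 35 gave as many genes past the adjusted threshold, 1 in the real split and 1 in the highest other. For lists called by camera, 34 of 35 splits gave as many, with 4 in the real split and 13 in the highest other. Chance cannot be excluded for any of these counts, and the list calls in particular are no more frequent than between other groups of 4.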

How the results depend on the processing

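The covariates and the joint removal of ischemia replicates 1 and 4 were chosen after seeing the data. Against 1 gene called, 0 passed with normexp, quantile normalization, no filter, the stricter filter, every probe, the replicate block, the covariates or both arrays left out, and 0 with each array left out. More passed with median scaling (2), eBayes with trend and robust (20), an adjusted p under 0.1 (3) and an unadjusted p under 0.01 with 1.5-fold (91). The chromosome 18 feature was not among the 2 genes, which are Pla1a and Chil3, nor among the 20. Against 2151 genes at an unadjusted p under 0.05, median scaling gave 1414, and each array left out gave 1613 to 2403. Against 4 lists called, 9 passed without a filter, 8 with every probe, 8 with trend and robust, 2 with the stricter filter, 7 with both arrays left out, 4 to 10 with each array left out and 0 with an estimated correlation or fry. The cause was not tested. Of 21 settings, 14 further lists were called by camera under some: unfolded protein response (10), astrocytes (7), interferon response (6), blood cells (4), inflammatory cytokines (4), respiratory chain (3), deep layer neurons (3), ribosomal proteins (3), cholesterol synthesis (2), subplate (2), microglia (1), antigen presentation (1), myelinating oligodendrocytes (1) and, of 20, choroid plexus (1). By list mean per array 0 lists passed under every setting run, which shows no stability: with 8 arrays, 23 of the 40 lists would have to reach the smallest p for any to pass. Array weights, trend and robust do not enter the list means, and this test was run neither for them nor for the covariates. The cell cycle and glucocorticoid lists kept their direction and camera call under 21 other settings, those 2 set tests apart, with differences from -0.30 to -0.18 and from 0.25 to 0.41. Normexp also brought Bub1 to -0.27, Ccl4 to -0.54, Gbp3 to -0.34, Cplx3 to -0.30 and Igf2 to 0.15. Its offset shrinks such dim probes by construction. The mean of a gene's probes was 0.13 for Sgms1, -0.20 for Fam13c and 0.00 for Dcx. Of 1744 values of named genes, 35 changed sign, in 11 genes that never passed. Whether replicate numbers pair the samples stays open, and the replicate number is also the slide column. Deviations of same-numbered samples correlated by 0.084, -0.055, 0.288 and 0.391. Replicates 3 and 4 correlated best with their own number, and replicates 1 and 2 did not. With the replicate block 0 genes passed and the 4 lists called stayed 4, and sign flips of 4 pairs cannot give a p under 0.125. Signal limits genes such as Chil3 and Slco1a4, which the control arrays did not measure above background.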

Other observations

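S100a8 and S100a9, calcium-binding proteins of neutrophils chosen after their values were seen, differed by 1.88 (SE 0.49, limma adjusted p = 0.270) and 1.47 (SE 0.50, limma adjusted p = 0.368) and did not pass. S100a8 was well above background on 2 of 4 control arrays and 4 of 4 ischemia arrays, and differed by 0.81 with normexp background correction. Slc13a4, a sulfate transporter of meninges and choroid plexus, lay 1.94 above the control mean in ischemia replicate 1 and 2.93 in ischemia replicate 4.

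The remaining lists were not called by camera. Mean differences below 0 were -0.06 for mitochondrial respiratory chain subunits, -0.06 for cytosolic ribosomal proteins, -0.11 for pericytes and smooth muscle, -0.04 for cholesterol synthesis, -0.06 for angiogenic signalling, -0.03 for reactive astrocyte markers, -0.02 for oligodendrocyte precursors, -0.01 for thalamus and hypothalamus, -0.02 for the glutamatergic synapse, -0.03 for olfactory bulb and rostral migratory stream, -0.03 for p53 and apoptosis, -0.01 for striatum and -0.01 for hippocampus. Differences above 0 were 0.03 for interneurons, 0.02 for immediate early genes, 0.05 for myelinating oligodendrocytes, 0.01 for GABA receptors and chloride transport, 0.02 for glycolysis enzymes and 0.02 for the NRF2 response. Antigen presentation and complement, Cajal-Retzius cells and heat shock proteins each lay within 0.01 of 0. With quantile normalization the sign of ribosomal proteins turned, to 0.02, and the respiratory chain differed by -0.02. The mean, the median and the test differed in sign in 11 of the 40 lists, of which 0 were called. In antigen presentation and complement, 4 members passed as higher and 2 as lower when adjusted over the list alone, in reactive astrocyte markers 2 as higher and 2 as lower, in pericytes and smooth muscle 2 as lower and in angiogenic signalling 1 as lower.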
